A study of Mus musculus with 14 samples.

How the data were processed

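The series holds 1 table of raw counts per gene for 14 RNA libraries, and all values here derive from it. Per the labels' protocols, RNA was extracted from cultured Eµ-Myc lymphoma cells or from lymphomas, libraries were made with a stranded mRNA kit, and paired ends were sequenced on a NextSeq instrument. Per the submitters' processing notes, the tools were STAR 2.4.0 and featureCounts of Subread 1.5.0-p3, on mm10 (GRCm38), and the deposited values are whole-number counts per gene, not normalized. The strand setting and the treatment of reads with several matches in the counting are not given in the sources used here. Reads of overlapping or antisense genes, such as Trp53 and Wrap53, and of near-identical copies, such as Hba-a1 and Hba-a2, Ccl21a, Eno1, Gapdh and several mitochondrial genes, could therefore be divided or lost, and their values are uncertain. Coordinates are those of the deposited table.

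All 14 columns were matched to a sample by title and 0 were left over. The table had 46959 gene entries and 100 entries of spike-in and phage sequences. The latter were left out of library sizes and tests, and held 0 spike-in counts and 5 to 534 phage counts per library. Samples fell into 3 groups, the cultured lines (12 libraries), the vehicle lymphoma (1) and the ASNase lymphoma (1). The labels name a different mouse for each line, and both lymphomas derive from line 506. In each library 3 counts correspond to 0.0897 to 0.124 CPM, the level that a count of 0 allows. Reads carry no molecular identifiers, so intervals and floors cover counting error only.

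Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3, and plotted with matplotlib 3.10.9 in Python 3.11.15. Genes were kept by filterByExpr on the groups, libraries were scaled by TMM, and edgeR's quasi-likelihood test (glmQLFit, glmQLFTest) was fitted to the 3 groups, with 11 residual degrees of freedom that all come from the lines. The contrasts were the mean of both lymphomas against the lines and the ASNase against the vehicle lymphoma. A second fit set line 506, and each other line in turn, against the remaining lines. Adjusted p-values follow Benjamini and Hochberg, with a threshold of 0.05. Log2 CPM used a prior count of 2. Pairs of single libraries were compared by size only, with a log2 ratio of at least 1 and 5 CPM or more in either library, and named genes have exact 95% binomial intervals. Variation among the lines was the SD of log2 CPM.

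The 32 gene lists covered pathways (amino acid response, aminoacyl-tRNA synthetases, aspartate, asparagine and glutamine metabolism, serine and one-carbon metabolism, glycolysis, oxidative phosphorylation, mitochondrial mRNAs, p53 targets, MYC targets, proliferation, interferon response, hypoxia, unfolded protein response, cholesterol synthesis, autophagy and lysosome, apoptosis regulators and tumour genes), B cell stages (pan-B, progenitor, mature, plasma), other cell types (T, NK, macrophage, neutrophil, dendritic, fibroblast, endothelium, erythroid, adipocyte, epithelium and muscle) and quality (immediate early and heat shock genes, X inactivation and Y-linked genes). They held 626 genes, of which 625 were found. Lists were tested with camera (preset correlation 0.01, and estimated) and fry. For pairs of single libraries a list's median over genes with at least 1 CPM was ranked among 10000 random lists drawn from 20 bins of mean expression. Relations across the lines used list means of scaled log2 CPM and 100000 permutations. The line of origin was examined by Spearman rho over the 500 most variable genes and by immunoglobulin V segments.

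Named genes followed a rule set with the lists, groups, tests and first alternatives before the data were examined. It takes the 8 largest increases and decreases past the threshold among genes with at least 10 CPM on the higher side, 3 genes per list by smallest p or, between the lymphomas, by largest ratio, and the 8 largest ratios each way at 20 CPM or more. For the lines it takes the 12 largest SDs at a mean log2 CPM of at least 5, for line 506 against the vehicle lymphoma the amino acid response list, for line 506 against other lines the 5 largest changes each way, and always Asns, Gapdh, Myc, Cdkn2a and Trp53. Immunoglobulin and T cell receptor segments were kept apart. Other genes in the text that belong to the lists, neighbours of named genes and genes under counts of 5 or fewer were named after their values were seen. Results that need an item withheld for evaluation are not reported.

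The edgeR comparisons, the size rule between the lymphomas and camera were tested on simulated counts of 17450 genes with known changes. Relations, random-list percentiles, variation among the lines and the line of origin were not simulated. All libraries were drawn as independent, whereas both lymphomas derive from line 506. Recovery and false calls therefore do not cover traits of that line. For lymphomas against lines, 18%, 70%, 88% and 90% of genes changed 2-, 4-, 8- and 16-fold were recovered, with 8 false calls. For ASNase against vehicle lymphoma with the spread of the lines these shares were 0%, 18%, 42% and 64%, with 4 false calls, and for line 506 against the other lines 2%, 38%, 58% and 80%, with 9 false calls. For ASNase against vehicle by size they were 48%, 90%, 94% and 94%, but 1957 unchanged genes also passed when the lymphomas were drawn with the spread of the lines. Camera called the 1 shifted list of 20 and no other. The simulated genes were drawn without correlation within lists, so this result does not cover false calls where genes of a list vary together. In the lists used here the estimated correlation ran from -0.10 (epithelium and muscle) to 0.69 (mitochondrially encoded mRNAs).

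Alternatives fixed beforehand were RLE scaling, other filters and floors, DESeq2, other prior counts, total-count scaling, immunoglobulin segments left out, each lymphoma alone, both lymphomas as 1 group, a test against a fold of 2, and line 506 left out. Chosen after seeing the data were fits without lines 549 and 688 or without lines 504 and 524, the removal of a loess trend (span 0.5) of log2 ratios on exon length, also for the list percentiles, and the thresholds of the checks in the closing section (under 0.5 CPM for a gene that is off, at least 10 CPM in other lines, in 9 or more of them where 1 line is singled out, 20 or more counts for the chi-square, 1 CPM for neighbouring genes).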

Results

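RNA sequencing measured gene expression in 14 libraries from Eµ-Myc lymphomas, a mouse model in which a Myc transgene under the immunoglobulin heavy chain enhancer gives rise to malignant B-lineage cells. There were 12 libraries of cultured lines, named for the transgenic mice 115, 136, 309, 504, 505, 506, 517, 524, 549, 649, 688 and 801. Each was grown for 24 h without treatment in a medium to which L-asparagine had been added. The other 2 libraries came from lymph node lymphomas that line 506 formed in wild-type mice. The first of these mice received vehicle (0.9% NaCl) and the second L-asparaginase (ASNase), an enzyme that breaks down asparagine, from day 7 after injection of the cells to the disease endpoint. Total counts ran from 24597337 to 32615111 in the lines, and were 27716078 in the vehicle lymphoma and 25691322 in the ASNase lymphoma. Genes with at least 1 count numbered 17050 to 18714 in the lines, 21648 in the vehicle lymphoma and 21642 in the ASNase lymphoma. Each line and each treatment had 1 library. Values are in CPM, the counts of a gene over each 1e6 counts of its library, after TMM scaling, with the SD over the lines where a mean over them is given.

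The first comparison asked how the tumours in the lymph node differed from the cells in culture. Transcripts of connective tissue, macrophages, vessels and T cells were higher in the lymphomas, and transcripts of cholesterol synthesis, cell division and tRNA charging were lower. Of these lower lists only cell division was also called by camera with an estimated correlation, with adjusted p = 0.215 for cholesterol synthesis and adjusted p = 0.120 for tRNA charging. Col1a1 and Col1a2, the chains of type I collagen, stood at 273 and 218 CPM in the vehicle lymphoma and at 602 and 579 CPM in the ASNase lymphoma, against 5 and 6 counts summed over the 12 lines. C1qb, a complement component made by macrophages, had no count in any line, and was at least 5640-fold higher in the vehicle and at least 11082-fold higher in the ASNase lymphoma, with 3 counts over the group of lines as the floor. Cyp51, an enzyme of cholesterol synthesis, fell from 271 ± 111 CPM in the lines (SD, n = 12) to 50.8 and 29.0 CPM in the vehicle and ASNase lymphomas (log2 fold change -2.82, SE 0.50, edgeR quasi-likelihood test, adjusted p = 0.00168). Tars, the threonyl-tRNA synthetase, fell from 168 ± 22.6 CPM (SD, n = 12) to 85.5 and 69.3 CPM (log2 fold change -1.13, SE 0.18, edgeR adjusted p = 0.000685).

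Of 17450 genes tested, edgeR with Benjamini-Hochberg adjustment called 4269 at an adjusted p under 0.05, 2340 higher and 1929 lower in the lymphomas. Of those called higher, 303 had no count in any line. The residual spread came from the lines alone, so each lymphoma was assumed to vary as a further, independent line would. Both derive from line 506, so they are not independent and that line is counted more than once among the tumours. Fits with a single lymphoma count the line once among the tumours, but a call in any of these fits can still reflect line 506 itself. With the ASNase lymphoma as the only tumour the test called 2012 genes, and with the vehicle lymphoma as the only tumour 1816.

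The largest increases among abundant genes were in extracellular matrix and macrophage genes. Besides Col1a1, Col1a2 and C1qb they were Bgn, Col4a1, Col4a2, Col6a1 and Postn. Col4a1 and Col4a2, the collagen chains of basement membranes, stood at 277 and 181 CPM in the vehicle lymphoma and 143 and 99.1 CPM in the ASNase lymphoma, against 5 and 2 counts over the lines. Bgn, the proteoglycan biglycan, had 1 count over the lines and 112 and 162 CPM in the vehicle and ASNase lymphomas. Postn, the matrix protein periostin, had no count in any line and was at least 3210-fold and 13787-fold higher in the vehicle and ASNase lymphomas, and Col6a1 was at least 5211-fold and 6363-fold higher. The largest decreases were in Rag1, Fads2, Tnfrsf26, Syde2, Mreg, 2900026A02Rik, Clic5 and Mfsd2a. Rag1, which cuts DNA in V(D)J recombination, was at 49.8 ± 50.8 CPM in the lines (SD, n = 12) and at 0.161 and 0.234 CPM in the vehicle and ASNase lymphomas (edgeR adjusted p = 0.0441). Line 506 itself had 6.52 CPM of Rag1, so part of this gap is a trait of that line. The rest of these genes stood at 16.1 (Mreg) to 132 CPM (Fads2) in line 506. Mreg fell from 26.3 ± 18.4 CPM to 1.45 and 1.24 CPM (SD, n = 12, edgeR adjusted p = 0.00167) and kept its call without either lymphoma. The other 7 lost theirs without the ASNase lymphoma, with edgeR adjusted p from 0.0657 for 2900026A02Rik to 0.218 for Mfsd2a, and Rag1, Syde2, Clic5 and Mfsd2a also lost theirs without the vehicle lymphoma.

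Of the 32 gene lists fixed before the data were examined, camera with a preset correlation of 0.01 called 19, with 10 higher and 9 lower in the lymphomas. Among the lists of other cell types, 21 of 22 tested fibroblast and reticular stroma genes rose (22 when adjusted over the list alone, camera adjusted p = 3.82e-27). For macrophages and monocytes 20 of 23 rose (20 over the list alone, adjusted p = 2.55e-18). Cd68, a lysosomal protein of macrophages, rose from 2.46 ± 0.686 CPM to 33.9 and 70.3 CPM in the vehicle and ASNase lymphomas (SD, n = 12, edgeR adjusted p = 3.05e-07). For neutrophils 12 of 14 rose (13 over the list alone, adjusted p = 2.02e-15), with Ngp, a granule protein, at 1 count over the lines and 3.99 and 1.60 CPM in the vehicle and ASNase lymphomas. For endothelium 13 of 20 rose (13 over the list alone, adjusted p = 1.21e-14), with Kdr, a receptor for vascular growth factors, at 1 count over the lines and 19.1 and 12.4 CPM in the lymphomas. For T cells 13 of 20 rose (16 over the list alone, adjusted p = 1.47e-13), among them Cd8a, a T cell co-receptor chain, with 1 count over the lines and 6.96 and 0.501 CPM. For dendritic cells 6 of 12 rose (8 over the list alone, adjusted p = 8.93e-06), with Fscn1, an actin-bundling protein, at 0.0426 ± 0.0684 CPM in the lines (SD, n = 12) and 17.4 and 4.91 CPM in the lymphomas.

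For NK and cytotoxic cells 1 of 12 rose (0 over the list alone, camera adjusted p = 8.93e-06), and that gene, Klrk1, lost its call without the vehicle lymphoma (edgeR adjusted p = 0.101) or without the ASNase lymphoma (0.0894). For adipocytes 5 of 9 rose (5 over the list alone, adjusted p = 0.000402). For erythroid cells 4 of 8 rose and 1 fell (5 and 1 over the list alone, adjusted p = 0.00117). Hba-a1, an alpha globin gene, rose from 6 counts over the lines to 99.4 and 58.5 CPM, and Klf1, an erythroid transcription factor, was at 0.382 ± 0.174 CPM in the lines (SD, n = 12) with 0 and 0.0668 CPM in the lymphomas. The call of Klf1 was lost without the vehicle lymphoma (edgeR adjusted p = 0.140). In the interferon response list 11 of 33 genes rose (13 over the list alone, camera adjusted p = 7.79e-06), with Oas2, an antiviral RNA sensor, at 0.0821 ± 0.0907 CPM in the lines (SD, n = 12) and 10.9 and 3.04 CPM in the lymphomas. The interferon list was not called with an estimated correlation (adjusted p = 0.269), and the other 9 higher lists were, with adjusted p between 1.95e-05 and 0.0399.

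Among the lower lists, 20 of 26 proliferation genes fell (23 over the list alone, with 1 higher, camera adjusted p = 3.76e-09), and this lower list alone was also called with an estimated correlation (adjusted p = 0.00165). Mcm4, part of the replicative helicase, fell from 349 ± 50.1 CPM to 148 and 150 CPM in the vehicle and ASNase lymphomas (SD, n = 12, edgeR adjusted p = 0.000388), and Bub1, a mitotic checkpoint kinase, from 122 ± 18.1 to 52.1 and 52.5 CPM. In the cholesterol synthesis list 19 of 21 genes fell (19 over the list alone, camera adjusted p = 4.10e-09), with a median log2 fold change of -2.15, and adjusted p = 0.215 with an estimated correlation. Of the cytosolic aminoacyl-tRNA synthetases, which charge tRNAs, 16 of 20 fell (19 over the list alone, adjusted p = 6.10e-08), with a median of -0.93 and adjusted p = 0.120 with an estimated correlation. Of the MYC targets 22 of 33 fell (27 over the list alone, adjusted p = 1.28e-09), with a median of -0.86 and adjusted p = 0.194 with an estimated correlation. Ran, a nuclear transport GTPase, fell from 852 ± 67.8 CPM to 460 and 438 CPM (SD, n = 12). Of the nuclear-encoded oxidative phosphorylation genes 26 of 47 fell (32 over the list alone, adjusted p = 1.83e-10), with a median of -0.58 and adjusted p = 0.185 with an estimated correlation. Atp5b, a subunit of the ATP synthase, fell from 1989 ± 236 CPM to 1121 and 1130 CPM (SD, n = 12).

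In the glycolysis list 11 of 23 genes fell and 1 rose (11 and 2 over the list alone, camera adjusted p = 0.0141), with adjusted p = 0.306 with an estimated correlation. Hk2, a hexokinase, fell from 113 ± 21.8 CPM to 51.9 and 41.0 CPM in the vehicle and ASNase lymphomas (SD, n = 12, edgeR adjusted p = 0.00213). Slc2a1, a glucose transporter, fell too (log2 fold change -1.26, SE 0.21, edgeR adjusted p = 0.00119). Hk3, a hexokinase of myeloid cells, rose from 0.0277 ± 0.0235 CPM to 4.16 and 6.11 CPM (SD, n = 12), and fry, which does not compare a list with other genes, gave this list the opposite direction (adjusted p = 0.00266). In the serine and one-carbon list 7 of 16 genes fell (7 over the list alone, camera adjusted p = 0.00847; adjusted p = 0.306 with an estimated correlation). Mthfd1, which interconverts folates, fell from 319 ± 54.9 to 169 and 139 CPM (SD, n = 12). In the hypoxia list 5 of 20 fell (5 over the list alone, camera adjusted p = 0.0315; adjusted p = 0.215 with an estimated correlation), and in the unfolded protein response list no gene was called by edgeR (0 of 19, 0 over the list alone, camera adjusted p = 0.0481; adjusted p = 0.658 with an estimated correlation).

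The amino acid response list, genes that the transcription factor ATF4 raises when amino acids are short, was not called (4 of 34 higher and 6 lower, 4 and 6 over the list alone, camera adjusted p = 0.140). Slc7a1, a transporter of basic amino acids, fell from 345 ± 46.4 to 177 and 187 CPM (SD, n = 12, edgeR adjusted p = 0.00188), and Vldlr, a lipoprotein receptor, had 2 counts over the lines and 0.870 and 1.87 CPM in the lymphomas. Asns, asparagine synthetase (chromosome 6, 7675169 to 7693254), was not called, at 107 ± 85.6 CPM in the lines (SD, n = 12) and 27.7 and 74.1 CPM in the vehicle and ASNase lymphomas (edgeR adjusted p = 0.567). Myc was at 1762 ± 702 CPM in the lines and 1401 and 1234 CPM in the lymphomas (SD, n = 12, edgeR adjusted p = 0.574), and Trp53 at 216 ± 91.7, 169 and 113 CPM (edgeR adjusted p = 0.742). Cdkn2a, the tumour suppressor locus of p16 and p19ARF, was at 73.7 ± 93.0 CPM in the lines and had 10 and 3 counts in the vehicle and ASNase lymphomas (SD, n = 12, edgeR adjusted p = 0.162). Gapdh fell from 1630 ± 309 to 1012 and 794 CPM (SD, n = 12, edgeR adjusted p = 0.0122), a call lost without the ASNase lymphoma (adjusted p = 0.149).

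The remaining lists were not called by camera. No gene of the pan-B cell list (0 of 14, smallest edgeR adjusted p 0.0530, for Cd37) or of the mature B cell list (0 of 23) passed the threshold. Counts higher and lower were 1 and 1 of 17 for progenitor B cells, 3 and 0 of 10 for plasma cells, 1 and 4 of 22 for aspartate, asparagine and glutamine metabolism, and 0 and 1 of 13 for mitochondrially encoded mRNAs. They were 3 and 3 of 26 for p53 targets, 4 and 1 of 21 for autophagy and lysosome genes, 0 and 2 of 21 for apoptosis regulators and tumour genes, and 2 and 1 of 17 for immediate early and heat shock genes. They were 1 and 0 of 6 for epithelium and muscle, and 0 and 0 of 5 for the X inactivation and Y-linked genes. Ctsd, a lysosomal protease, rose to 243 and 447 CPM in the vehicle and ASNase lymphomas (log2 fold change 2.15, SE 0.21, edgeR adjusted p = 1.15e-05). Kit, a receptor of progenitor and mast cells, had no count in any line and was at least 448-fold higher in the vehicle and 172-fold higher in the ASNase lymphoma, but lost its call without either lymphoma (edgeR adjusted p = 0.0748 and 0.0523). The median and the camera direction differed in sign for p53 targets (0.21, down), the pan-B cell list (0.15, down) and the epithelium and muscle list (-0.56, up).

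**Figure D1:**
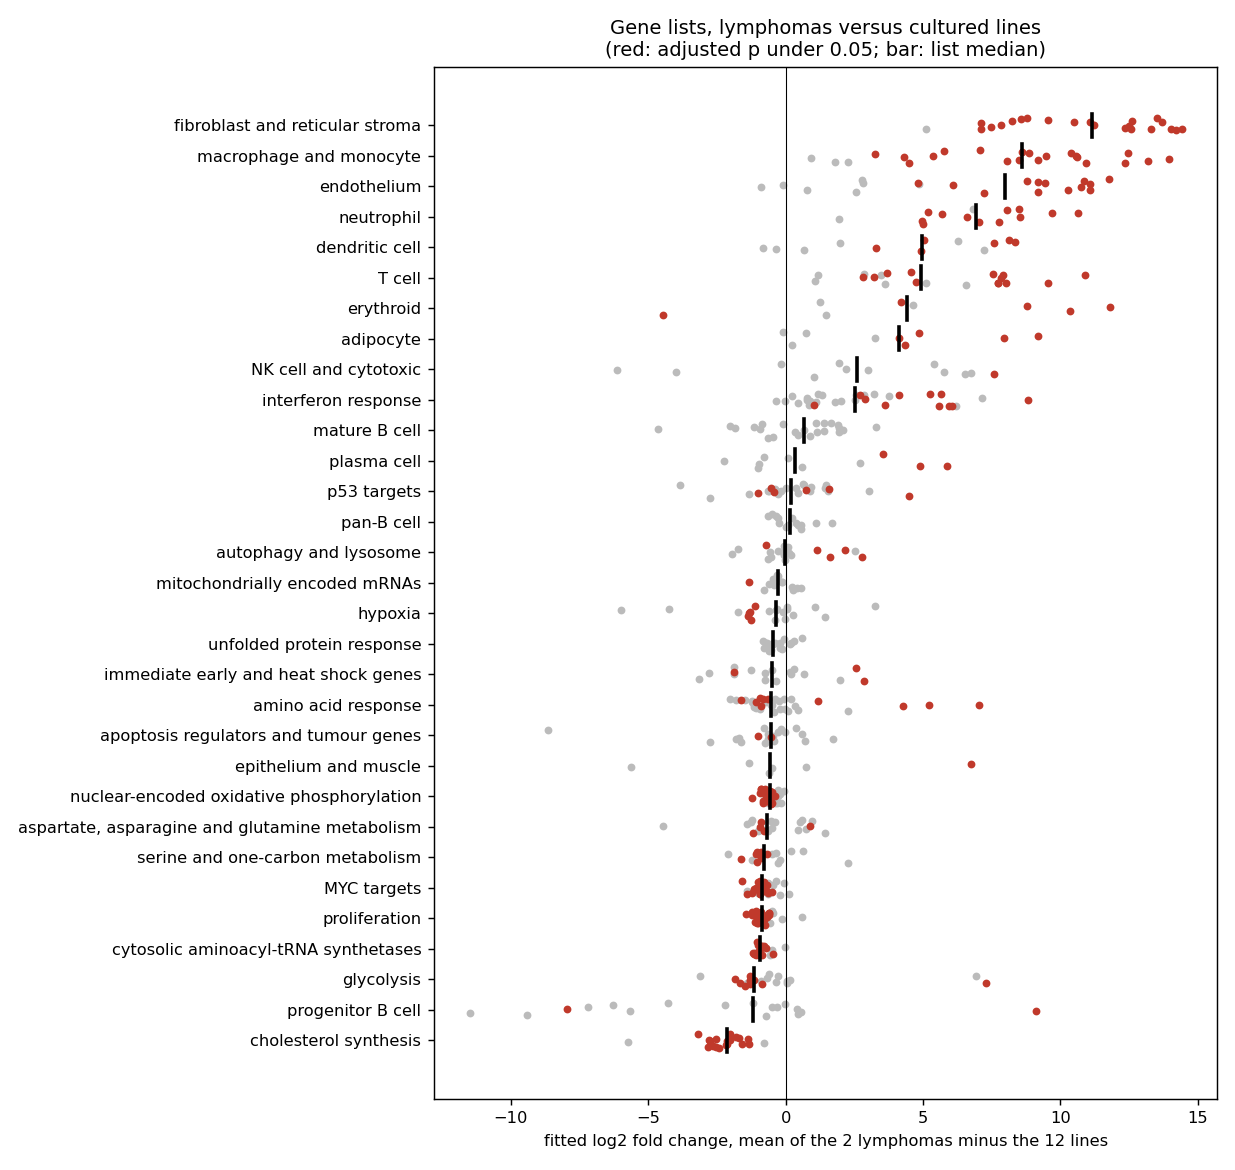
Fitted log2 fold changes (horizontal axis, mean of the 2 lymphomas minus the 12 lines) of the genes of 31 lists (the X inactivation and Y-linked list, at a median of -10.57, is not drawn), with red points for edgeR adjusted p under 0.05, grey points for other genes and a black bar at each list's median. The fibroblast, macrophage and endothelium lists lie far to the right and the cholesterol synthesis list farthest to the left of those drawn, at a median of -2.15; fitted values of genes with no count in the lines depend on the prior count.

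The comparison of treatments set the ASNase lymphoma against the vehicle lymphoma, 1 library each, so no difference here has a replicate check and no p is given across genes. Asns, which makes asparagine from aspartate, was 2.68-fold higher in the ASNase lymphoma (95% counting interval 2.47 to 2.90), at 74.1 against 27.7 CPM, beside 62.8 CPM in line 506 in culture. T cell genes were lower, with a median log2 ratio of -2.64, and macrophage genes were higher, with a median of 0.95. Glycam1, an adhesion ligand of the high endothelial venules of lymph nodes, was 0.0361-fold as abundant (0.0237 to 0.0530), with 27 against 775 counts. Mmp2, a matrix-degrading protease, was 5.86-fold higher (5.00 to 6.90), at 34.3 against 5.86 CPM. Intervals are exact binomial ones and cover counting error only.

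By size, a log2 ratio of at least 1 with 5 CPM or more in either lymphoma, 487 of 10561 genes differed, 281 higher and 206 lower in the ASNase lymphoma. A floor of 1 CPM gave 1066 genes and a floor of 20 CPM 190. The share of higher genes was 57.7% at first, 51.4% and 62.1% at these floors, 64.9% with total-count scaling, and 50.5% once the gene length trend was taken off, so an excess of higher genes is not firm. Set against the spread of the lines, which measures whether different lines would differ as much and not how mice treated alike vary, edgeR called 0 of 17450 genes (234 at an unadjusted p under 0.05), and DESeq2 called 4, Blm, Trim23, Lnpep and Cenpq, all higher in the ASNase lymphoma. These 4 were named after their values were seen.

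Among genes with 20 CPM or more in either lymphoma, the largest increases after Mmp2 were in Sepp1, Postn, Zc3h6, Slc23a1, Fcna, Mrc1 and Gpnmb, between 4.86-fold for Sepp1 (4.67 to 5.05), a selenium carrier, and 3.75-fold for Gpnmb (3.29 to 4.28), a glycoprotein of macrophages. Mrc1, the mannose receptor of macrophages, was 4.09-fold higher (3.70 to 4.52). At the same floor, the largest decreases after Glycam1 were in Itgb7, Enpp2, Clu, Fcmr, Fos, Ifi27l2a and Ms4a1, between 0.176-fold for Itgb7 (0.144 to 0.215), an integrin chain of lymphocytes that home to the gut, and 0.298-fold for Ms4a1 (0.276 to 0.323), which encodes CD20. Enpp2, the enzyme autotaxin, was at 4.71 against 24.5 CPM, and Clu, which encodes clusterin, at 13.4 against 66.7 CPM.

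List medians were placed among those of 10000 random lists of the same size matched on mean expression, as a description of these libraries. In the T cell list 6 of 8 genes at the floor were lower by size and 0 higher (percentile 0), with Cd8a at 0.501 against 6.96 CPM and Trbc2, a T cell receptor constant segment, at 1.00 against 10.0 CPM. The dendritic cell list had a median of -1.65 (percentile 0, 1 of 3 lower), with Fscn1 at 4.91 against 17.4 CPM. In the NK and cytotoxic list only 2 genes reached 1 CPM, and Ccl5, a chemokine of T and NK cells, stood at 0.702 against 5.25 CPM. In the macrophage list 8 of 20 genes were higher and 1 lower (percentile 100), with Cd163, a haemoglobin scavenger receptor, 8.79-fold higher (6.08 to 13.1) and Mertk, a receptor for apoptotic cells, 3.15-fold higher (2.70 to 3.69). The fibroblast and reticular stroma list had a median of 0.52 (percentile 100, 6 higher and 1 lower of 19), with Lum, the proteoglycan lumican, 8.41-fold higher (5.70 to 12.8) and Ccl21a, a chemokine of lymph node stroma, 0.300-fold as abundant (0.274 to 0.329). The endothelium list had a median of -0.76 (percentile 0, 2 of 18 lower), with Lyve1, a lymphatic receptor, 0.298-fold as abundant (0.246 to 0.360).

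Among B cell and signalling lists, the mature B cell list had a median of -0.76 (percentile 0, 6 of 20 lower), with Fcer2a, the low-affinity IgE receptor, at 0.167 against 9.89 CPM and Cr2, a complement receptor, at 0.468 against 5.06 CPM. Line 506 in culture had 0 counts of Fcer2a and Cr2. Whether these transcripts came from the lymphoma cells or from B cells of the host was not tested. The pan-B cell list had a median of -0.38 (percentile 0.05, 1 of 14 lower), with Blk, a B cell kinase, at 18.0 against 51.0 CPM and Ebf1, a B lineage transcription factor, at 147 against 82.4 CPM. The plasma cell list stood at -0.38 (percentile 1.53, 2 of 9 lower) and the progenitor B cell list at -0.11 (percentile 36.8, 1 of 6 higher), or 0.02 with total-count scaling. Immediate early and heat shock genes, which respond within minutes to stress or handling, had a median of -0.99 (percentile 0, 6 of 13 lower), with Egr1 at 12.0 against 38.3 CPM and Fosb at 3.61 against 19.7 CPM. The interferon response list stood at -0.63 (percentile 0, 3 of 12 lower), with Oas2 at 3.04 against 10.9 CPM.

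Among metabolic lists, 8 of 20 cholesterol synthesis genes were lower and 0 higher (median -0.91, percentile 0), with Sqle, squalene epoxidase, 0.385-fold as abundant (0.352 to 0.421) and Fdft1, squalene synthase, 0.378-fold (0.326 to 0.436). The glycolysis list stood at -0.36 (percentile 0.0700, 1 of 19 lower), with Pfkl, a phosphofructokinase, at 42.4 against 100 CPM. The amino acid response list stood at -0.03 (percentile 59.4), or 0.03 with total-count scaling, and Asns was its only member of 25 past the size rule, while Atf4 was at 232 against 237 CPM, Ddit3 at 5.45 against 7.60 CPM and Psat1, an enzyme of serine synthesis, at 230 against 162 CPM. The list of aspartate, asparagine and glutamine metabolism stood at -0.15 (percentile 21.4, Asns alone higher of 18), with Glul, glutamine synthetase, at 190 against 128 CPM. The serine and one-carbon list stood at -0.04 (percentile 57.9, 0.02 with total-count scaling), the aminoacyl-tRNA synthetases at -0.17 (percentile 10.1), and oxidative phosphorylation genes at -0.19 (percentile 1.54, or 29.8 once the gene length trend was taken off). The mitochondrially encoded mRNAs stood at 0.48 (percentile 100.0, 1 of 12 higher), but several of them share sequence with nuclear copies and are uncertain.

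For the remaining lists the medians were -0.18 for MYC targets (percentile 7.61), -0.09 for proliferation (percentile 42.4), -0.09 for hypoxia (percentile 37.4), -0.19 for the unfolded protein response (percentile 9.22), 0.16 for autophagy and lysosome genes (percentile 97.0) and 0.00 for p53 targets (percentile 66.3). They were -0.18 for apoptosis regulators and tumour genes (percentile 12.7), -0.74 for neutrophils (percentile 0.800), -0.45 for erythroid cells (percentile 3.09) and -0.26 for adipocytes (percentile 16.7). Only 2 epithelium and muscle genes and 1 gene of the X inactivation and Y-linked list were measured. Log2 ratios rose with exon length (Spearman rho 0.319 across genes, which are not independent), from a median of -0.25 in the shortest of 5 length classes to 0.21 in the longest. Myc was at 1234 against 1401 CPM, Trp53 at 113 against 169 CPM and Gapdh at 794 against 1012 CPM.

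**Figure D2:**
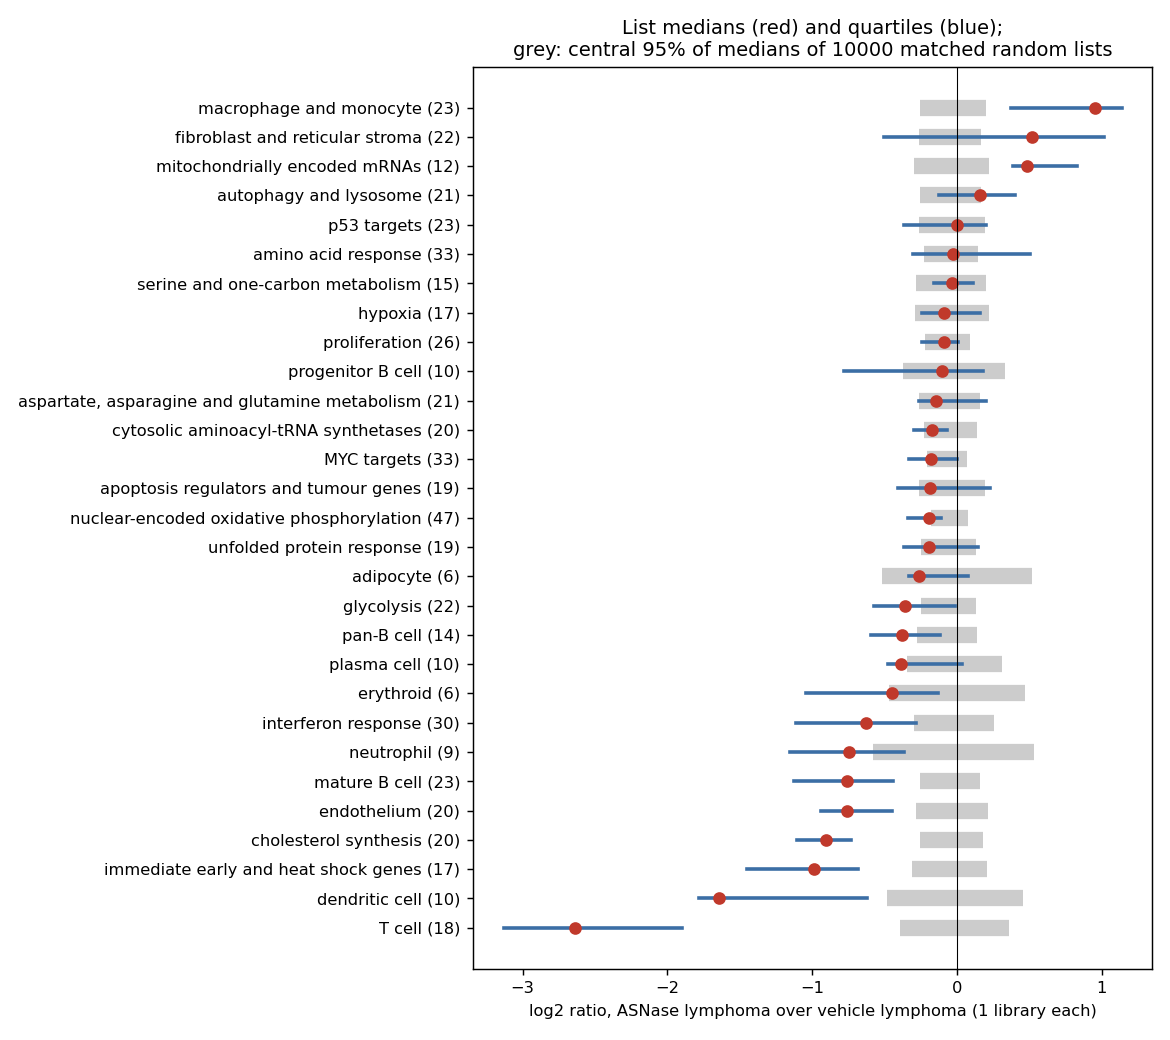
Median log2 ratio of each list (red points) with its quartiles (blue lines), ASNase over vehicle lymphoma, 1 library each; the number of genes measured is in brackets and grey bars hold the central 95% of medians of 10000 matched random lists. The T cell median of -2.64 lies far below its grey bar and the macrophage median of 0.95 above it, while the amino acid response median of -0.03 lies within it.

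The vehicle lymphoma was then set against line 506 in culture, the same line with and without a host, again with 1 library each and no replicate check. Asns was lower in the vehicle lymphoma, at 27.7 against 62.8 CPM (0.441-fold, 95% counting interval 0.406 to 0.478), and 1.18-fold higher in the ASNase lymphoma than in line 506 (1.11 to 1.26). Some other amino acid response genes were lower by size in the ASNase lymphoma than in line 506. They were Psat1 (0.364-fold, 0.354 to 0.375), Phgdh (0.448-fold), Psph (0.495-fold), Mthfd2 (0.300-fold), Slc7a1 (0.483-fold), Slc1a4 (0.390-fold), Aldh18a1 (0.388-fold) and Cth (0.367-fold). TMM factors were 1.17 for the ASNase lymphoma and 0.92 for line 506, so scaling by total counts would raise these ratios. Those nearest the rule, such as Psph, Slc7a1 and Phgdh, would then fall short of it. Ddit3 (2.43-fold) and Ddit4 (2.27-fold) were higher. The rest of the list at the floor did not pass either way. Among these were Atf4 (0.618-fold), Shmt2 (0.699-fold), Slc7a5 (0.601-fold), Gpt2 (1.64-fold) and Pycr1 (1.83-fold). Of 25 amino acid response genes at the floor, 10 were lower by size and 2 higher in the vehicle lymphoma. The lower ones were Asns, Psat1 and Phgdh of serine synthesis, Mthfd2 of folate metabolism, the transporters Slc7a5, Slc7a1, Slc38a2 and Slc1a4, Aldh18a1 of proline synthesis and Cth of cysteine synthesis. Psat1 stood at 162 against 632 CPM (0.256-fold, 0.248 to 0.264) and Cth at 5.25 against 24.0 CPM (0.219-fold, 0.184 to 0.260). The higher ones were the stress regulators Ddit3, 3.39-fold (2.57 to 4.53), and Ddit4, 2.80-fold (2.64 to 2.98). Atf4 stood at 237 against 375 CPM.

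By size 3109 of 10493 genes differed, 1838 higher and 1271 lower, with 59.1% of them higher. Scaling by total counts alone raised the median log2 ratio over the genes at the floor from -0.12 to 0.19 and the higher share to 80.1%. Under that scaling 4 of the 10 lower amino acid response genes (Psat1, Mthfd2, Aldh18a1 and Cth) and both higher ones still passed, with Asns at -0.89. With RLE scaling Slc7a5 fell short of the rule, at -0.98. A floor of 1 CPM gave 5030 genes, 70.7% of them higher, and a floor of 20 CPM gave 1865, 42.9% of them higher, so which direction prevails depends on the floor. Of the lists of other cell types, 18 of 19 macrophage, 18 of 18 fibroblast, 17 of 18 endothelium, 8 of 8 T cell and 4 of 4 erythroid genes were higher by size in the vehicle lymphoma. No adipocyte gene passed the rule (0 of 3, median log2 ratio 0.26, percentile 23.4). Of 3 dendritic cell genes 1 was higher and 1 lower. In the mature B cell list 14 of 20 genes were higher and 1 lower (percentile 100). Here too, B cells of the host were not told apart from the lymphoma cells. In the cholesterol synthesis list 19 of 20 were lower (percentile 0), and in the hypoxia list 10 of 16 were lower and 2 higher (percentile 0). In the glycolysis list 10 of 19 were lower (percentile 0.01). Of the proliferation genes 6 of 26 were lower (percentile 5.28), with a median of -0.70, or -0.41 with total-count scaling. Lower genes numbered 5 of 47 for oxidative phosphorylation (percentile 5.37). They numbered 13 of 33 for MYC targets (percentile 0.125) and 7 of 20 for aminoacyl-tRNA synthetases (percentile 0.19). Of the interferon response genes 10 of 12 were higher (percentile 99.98). Immediate early and heat shock genes, a sign of stress or handling, had 6 of 15 higher and 4 lower (median log2 ratio 0.82, percentile 99.1).

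The 12 lines form 1 untreated group, and each gene's spread over them was measured as the SD of log2 CPM. Among 8586 genes with a mean log2 CPM of at least 3, 541 had an SD of at least 1 over the lines. Among the genes with the largest SD were Reln, Mtap, Trp53, Asns, Cplx2, Foxf2, Asrgl1, Cd74, Thbd and Celsr2, with SDs from 4.31 for Reln, a secreted matrix protein, to 2.72 for Celsr2. Mtap, which salvages methionine (chromosome 4, 89137122 to 89181081), had 0.0339 CPM in line 506 and 0 in line 688, against 57.9 to 292 CPM in the others. Its neighbour Cdkn2a (89274471 to 89294653) was at or under 0.0387 CPM in lines 506, 549 and 688 and reached 217 CPM in line 517. Trp53 (chromosome 11, 69580359 to 69591873) was at 0.0718 CPM in line 524, 68.8 CPM in line 517 and at least 193 CPM elsewhere. Asns had 1 count (0.0317 CPM) in line 649 and 31.1 to 274 CPM in the others, and Asrgl1, an enzyme that splits asparagine, also had 1 count in line 649 and at least 23.0 CPM elsewhere. Cd74, the invariant chain of MHC class II, ranged from 8.02 CPM in line 136 to 4513 CPM in line 524.

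In the progenitor B cell list 5 of 6 genes at this floor had an SD of at least 1 (median SD 2.57), and in the mature B cell list 7 of 12 (median SD 1.22). None of the aminoacyl-tRNA synthetases (0 of 20), oxidative phosphorylation genes (0 of 47), MYC targets (0 of 33), proliferation genes (0 of 26) or cholesterol synthesis genes (0 of 20) did. In the amino acid response list 3 of 22 did. The count of 541 became 324 without lines 504 and 524, 283 with the median absolute deviation and 1172 with a floor of 1.

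**Figure D3:**
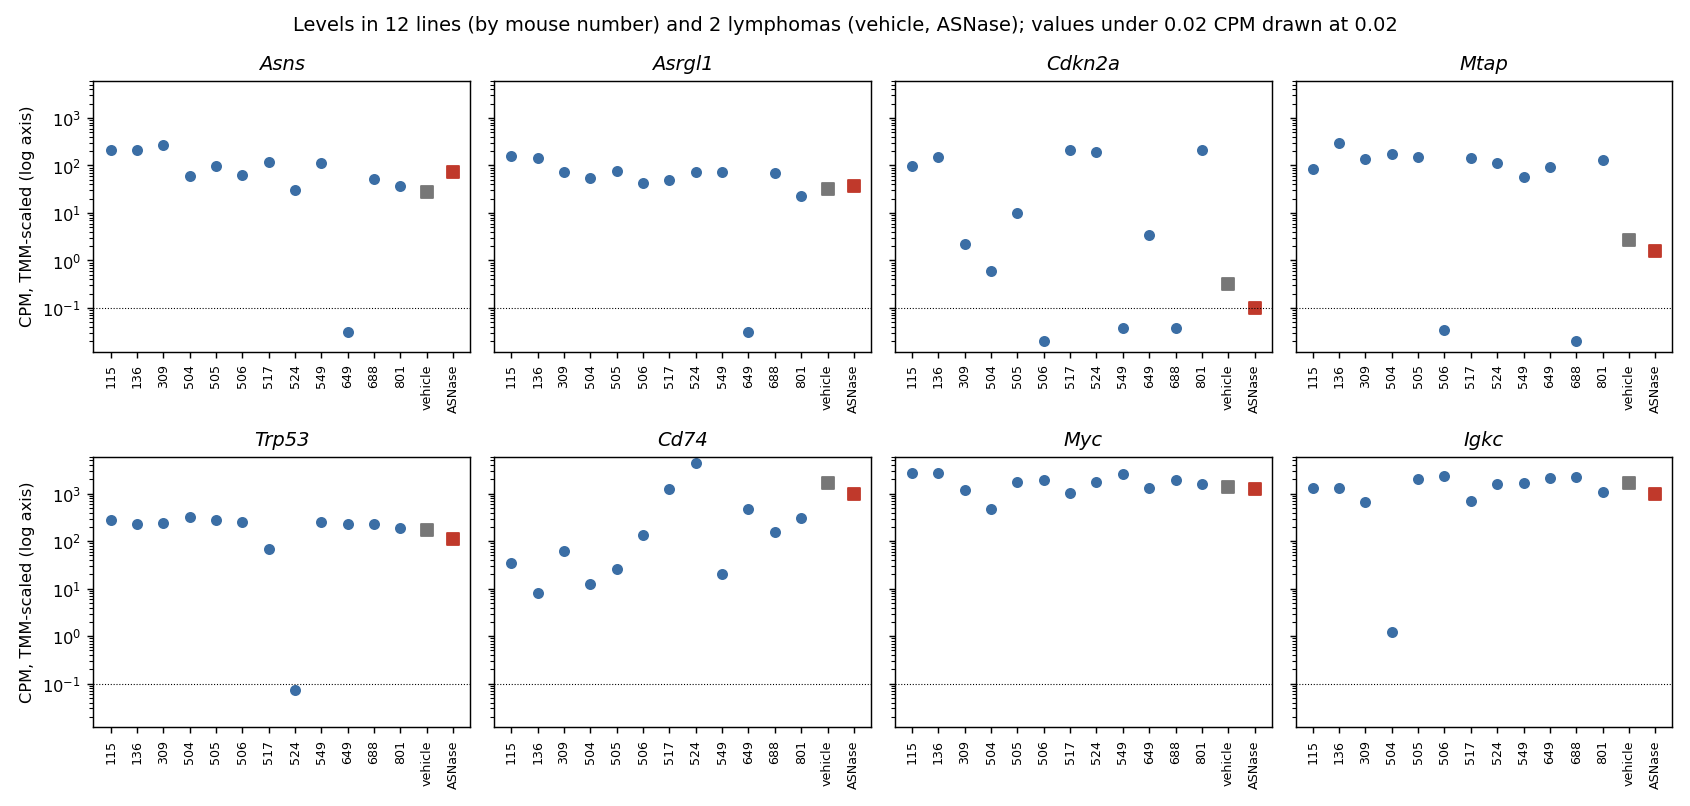
Levels of 8 genes in the 12 lines (blue points, by mouse number) and in the vehicle (grey square) and ASNase (red square) lymphomas, in CPM on a log axis; values under 0.02 CPM are drawn at 0.02 and the dotted line marks 0.1 CPM. Asns and Asrgl1 drop out in line 649, Mtap in lines 506 and 688, and Trp53 in line 524, while Asns lies at 27.7 CPM in the vehicle and 74.1 CPM in the ASNase lymphoma.

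Across the 12 lines, lines with more Asns had more of the enzymes of serine synthesis, and lines with more Myc had more of its targets. Asns went with the mean of Phgdh, Psat1 and Psph (Pearson r 0.726, permutation p = 0.00015, adjusted p = 0.0008; Spearman rho 0.832, permutation p = 0.00126). It also went with the other amino acid response genes (r 0.661, permutation p = 0.0131, adjusted p = 0.0219; rho 0.776, permutation p = 0.0043) and with the aminoacyl-tRNA synthetases (r 0.612, permutation p = 0.00786, adjusted p = 0.0190; rho 0.734, permutation p = 0.00839). Without lines 649 and 309, the farthest from the median of Asns, r was 0.804, 0.737 and 0.853. Myc went with the MYC targets (r 0.850, permutation p = 0.00077, adjusted p = 0.00257; rho 0.818, permutation p = 0.00188) and with glycolysis (r 0.606, permutation p = 0.0316, adjusted p = 0.0451; rho 0.783, permutation p = 0.00366), with r of 0.702 and 0.693 without lines 504 and 517. Glycolysis went with oxidative phosphorylation (r 0.871, permutation p = 0.00016, adjusted p = 0.0008; rho 0.902, permutation p = 0.00013), with r of 0.827 without lines 136 and 649. Without lines 549 and 688, a setting chosen after seeing the data because their profiles are close to that of line 506, the relations of Asns with the other amino acid response genes (adjusted p = 0.0565) and of Myc with glycolysis (adjusted p = 0.0925) were no longer called.

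Progenitor and mature B cell genes ran against each other (r -0.757, permutation p = 0.00952, adjusted p = 0.0190; rho -0.490, permutation p = 0.110), but the relation rests on lines 524 and 504, since r was -0.240 without them. Not called among the 10 relations were Asns with Atf4 (r 0.565, permutation p = 0.0863, adjusted p = 0.108; rho 0.594, permutation p = 0.0460; r 0.458 without lines 649 and 309), Cdkn2a with p53 targets (r -0.471, permutation p = 0.121, adjusted p = 0.134; rho -0.399, permutation p = 0.200; r -0.662 without lines 506 and 549) and MYC targets with proliferation (r -0.253, permutation p = 0.430, adjusted p = 0.430; rho -0.063, permutation p = 0.849; r -0.158 without lines 504 and 524). Tests were two-sided, with 100000 resamples.

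Line 506, the one engrafted, was compared with the other 11 lines. In line 506 Cdkn2a had no counts and Mtap 1, Asns stood at 62.8 CPM against a mean of 111 CPM in the others, Myc at 1930 against 1746 CPM and Trp53 at 256 against 212 CPM. No gene was called by edgeR (0 of 15648, 126 at an unadjusted p under 0.05), and DESeq2 called 18, all lower in line 506. The spread came from the other 11 lines alone, of which 549 and 688 are close to line 506 (rho 0.988 and 0.989 over all filtered genes). In simulated counts this test recovered 2% of genes changed 2-fold and 38% of those changed 4-fold, so the count of 0 says little. Without lines 549 and 688, a setting chosen after seeing the data, edgeR called 4 genes, Ighv5-17, Ighv5-2 and Mtus2 higher and Mtap lower (edgeR adjusted p from 0.00026 to 0.0351). The same fit for each other line called 621 genes for line 524 and 595 for line 504, 0 for line 549 (49 at an unadjusted p under 0.05), 0 for line 688 (192 at an unadjusted p under 0.05) and 3 to 23 for the rest.

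Both lymphomas carried the immunoglobulin V segments of line 506. Ighv5-17 took 88.2% of heavy chain V counts in line 506, 82.5% in the vehicle and 88.3% in the ASNase lymphoma, and Igkv9-120 took 93.3%, 89.6% and 91.6% of kappa V counts. Over the 500 genes most variable among the lines, the vehicle lymphoma had its highest Spearman rho across genes with line 506 (0.570), next to line 688 (0.568), and the ASNase lymphoma likewise (0.611 and 0.606). Over all filtered genes line 649 came first (0.905 and 0.908) and line 506 second (0.900 and 0.903), and without immunoglobulin segments line 688 came first for the vehicle lymphoma (0.565 against 0.562). Neither segment singles out line 506, since Ighv5-17 also led in lines 688 (87.0%) and 549 (65.0%), and Igkv9-120 in lines 688 (98.2%), 649 (54.8%) and 549 (51.5%). Mtap, with 1 count in line 506, was at 2.71 and 1.60 CPM in the vehicle and ASNase lymphomas.

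**Figure D4:**
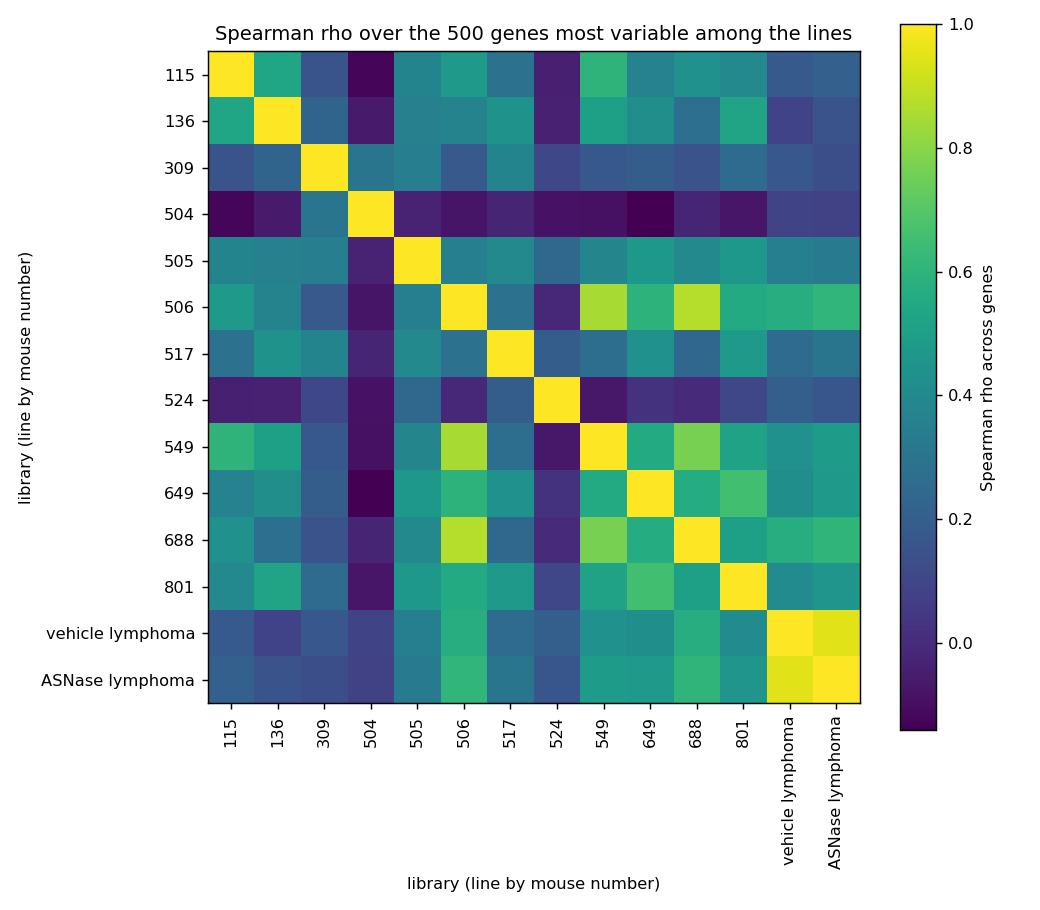
Spearman rho across the 500 genes most variable among the lines, for each pair of the 14 libraries (lines by mouse number, then the vehicle and ASNase lymphomas), on a colour scale. The lymphomas are closest to each other (0.947), and the highest value among the lines is that of lines 506 and 688 (0.873), followed by lines 506 and 549 (0.850).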

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

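Fits without lines 549 and 688 or without lines 504 and 524 and the removal of the gene length trend were chosen after the results were seen; the other settings were fixed before the data were examined. No paired analysis was possible because the groups share only the number 506, with 1 library each. Of 106 genes named for lymphomas against lines, 84 were called, 15 of these lost the call without the vehicle lymphoma and 27 without the ASNase lymphoma, and no gene reversed. Called genes shared with the first fit in the same direction numbered 4028 of 4156 with RLE, 3542 of 4375 with DESeq2, 3768 of 3785 without line 506, 3362 of 3394 without lines 549 and 688 and 4207 of 5714 without lines 504 and 524, with 0 opposite calls in each. Each lymphoma alone gave 1816 to 2012 called genes, with 1 tumour library in place of 2, and a test against a fold of 2 gave 969, all among those called first, with 925 higher and 44 lower. Of the calls, 54.8% were higher in the first fit and 46.8% with DESeq2, so the balance between higher and lower calls depends on the test. An estimated correlation left 10 of the 19 lists. Under fry the direction reversed for glycolysis (adjusted p = 0.00266), autophagy and lysosome (0.0256), progenitor B cells (8.17e-05), p53 targets (0.0662), pan-B cells (0.255) and the amino acid response (0.728), without the ASNase lymphoma for pan-B cells (0.948; 0.682 without the vehicle lymphoma), and without the vehicle lymphoma for epithelium and muscle (0.997; 0.943 without the ASNase lymphoma); the cause was not tested.

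By size the ASNase comparison gave 1066 genes at a floor of 1 CPM and 190 at 20 CPM, and line 506 against the vehicle lymphoma 5030 and 1865, since the floor sets which genes are counted. Against the spread of the lines DESeq2 called 4 genes in place of 0 between the lymphomas and 18 in place of 0 for line 506, which without lines 549 and 688 gave 4 with edgeR; the cause was not tested. The count of variable genes became 1172 with a floor of 1, 283 with the median absolute deviation and 324 without lines 504 and 524. Line 506 ranked 2 in place of 1 for both lymphomas over all filtered genes, and 2 for the vehicle lymphoma without immunoglobulin segments. The count of called relations stayed within 1.5 times under its 5 alternatives, but without lines 549 and 688 Asns with the amino acid response (adjusted p = 0.0565) and Myc with glycolysis (adjusted p = 0.0925) were no longer called. With 1 library per treatment, depth limits only low genes; a gene needs about 0.1 CPM to exceed 3 counts.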

Other observations

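The test of the genes beside Asns was set before its result was seen; the other tests of explanations in this part, and the genes singled out in it, were chosen after. Several lines lacked transcripts of neighbouring genes. Line 524 had 0 counts of Wrap53 and 2 of Trp53 on chromosome 11, with Efnb3 and Fxr2 on either side at 26.1 and 59.6 CPM. In lines 506 and 688 Mtap, Gm12606 and Cdkn2a on chromosome 4 had at most 1 count each, with Klhl9 at 59.7 and 54.3 CPM and Gm12669 at 9.71 and 9.06 CPM on either side. In line 549 Cdkn2a had 1 count and Mtap stood at 48.4% of the other lines' mean.

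Line 504 stood apart in B cell stage genes. Dntt, which adds nucleotides at V(D)J junctions, was at 1006 CPM there and at most 1.37 CPM in the other lines. Igll1 and Vpreb1, which form the surrogate light chain of pre-B cells, were at 425 and 298 CPM, and Igkc, the kappa constant region, at 1.21 CPM, against 672 to 2322 CPM elsewhere. Line 524 held the highest Ms4a1 (546 CPM) and no counts of Rag1 or Igll1. Of genes at 10 CPM or more in at least 9 other lines, 37 were off in line 504, 34 in line 524, 15 in line 505 and 12 in line 115, and 0 to 5 in each other line. A gene can count for more than 1 line under this rule, as Plekha5 did for lines 115, 504 and 524.

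Lines 506 and 688, named for different mice, had the same leading V segments, Ighv5-17 (88.2% and 87.0% of heavy chain V counts) and Igkv9-120 (93.3% and 98.2% of kappa V counts), and line 549 had both beside others (65.0% and 51.5%). The others include Ighv13-2, at 25.7% in line 549 and 99.8% in line 115, and rho over all filtered genes between lines 115 and 549 was 0.976. The kappa segment is the weaker sign, since it also led in line 649 (54.8%), whose heavy chain segment was Ighv1-80 (99.6%). The tables argue against one library deposited under both names, since the counts of lines 506 and 688 differed by a chi-square of 20.9 per degree of freedom, where sampling alone gives about 1, although pairs among the other 9 lines gave 105 to 376. They also argue against chance use of the same segments by unrelated tumours, since rho over all filtered genes was 0.989, above the 0.968 of the closest of 36 other pairs. A candidate explanation that stays open is one clone of cells grown under different names. Of the genes off in line 506, 93.3% (14 of 15) were off in line 688 too, against at most 69.0% in pairs of the other lines, but of the 23 genes off in line 688 only 14 were off in line 506. These matches are not all separate. Kdm5d, Eif2s3y and Ddx3y lie on the Y chromosome and also had 0 CPM in line 115, and Mtap and Cdkn2a are neighbours. A mixing of cultures, in line 549 above all, was not tested and stays open too. No biological explanation was tested, since the labels give the lines no other property.

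In line 649 Asns had 1 count where 3672 would be expected from the other lines, so shallow sequencing is excluded. A deletion of every copy that reaches the neighbouring genes is argued against. Sdhaf3 and C1galt1, the nearest expressed genes, 632190 and 151588 bp away, stood at 58.5% and 126% of the other lines' mean. On the side of Sdhaf3, Gm5873 and Shfm1 stood at 70.9% and 66.0%, so the test cannot exclude a loss of 1 copy reaching that side. A low amino acid response is argued against as the whole source, since the other genes of that list had a median log2 difference of only -0.35 (interquartile range 0.41, 25 genes). The response was nonetheless low in line 649. Its mean scaled score was -0.69, with only line 801 lower (-0.72), and its score for Phgdh, Psat1 and Psph was the lowest of the lines (-1.34). A smaller deletion or silencing of Asns may remain, and neither was tested.

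Between the ASNase and the vehicle lymphoma, the average gene length trend is argued against as the source of the difference in Asns, whose log2 ratio was 1.42 before and 1.47 after its removal, and of most calls by size, 83.8% of which (408 of 487) were kept. That trend was small beside the size rule, at -0.16 in the shortest and 0.21 in the longest decile of length. An effect that differs among genes of like length was not tested. A higher amino acid response as a whole is argued against by the median log2 ratio of the other amino acid response genes, -0.0303 (SD 0.71, 32 genes). The list was split, with quartiles of -0.30 and 0.51. In the ASNase against the vehicle lymphoma Pycr1 (19.1 against 12.1 CPM), Gpt2 (14.5 against 9.82) and Cth (8.79 against 5.25) were higher. Ddit4 (108 against 133 CPM), Sesn2 (5.88 against 9.24) and Cebpb (3.81 against 6.86) were lower. A rise in part of the list stays open. A lower share of lymphoma cells alone, with the mix of other cells unchanged, would raise markers of all other cell types. The T cell median was -2.64 while the macrophage median was 0.95, which argues against that narrow case only. A lower share together with a changed mix stays open. The pan-B and mature B cell medians were -0.38 and -0.76, the fibroblast median was 0.52 and the endothelium median -0.76. The mature B cell median is a poor measure of the lymphoma share. Line 506 in culture had 0 counts of its members Fcer2a and Cr2, 22 of Ms4a1 and 4 of H2-DMa. Mtap, with 1 count in line 506, was lower in the ASNase than in the vehicle lymphoma (1.60 against 2.71 CPM). That goes against a lower share, but it is 1 gene at a low level and cannot decide. A change in the macrophages or fibroblasts themselves stays open too. ASNase as the cause of the Asns difference may hold, but with 1 lymphoma per treatment it cannot be separated from a difference between mice. The lymphoma libraries hold transcripts of host cells too, and which cells held the added Asns transcripts was not tested.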
